A study of Mytilus galloprovincialis with 11 samples.

How the data were processed

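RNA of digestive gland, the main digestive and detoxifying organ of bivalves, was measured in the Mediterranean mussel Mytilus galloprovincialis on a 1-colour (Cy3) Agilent oligonucleotide array with 59971 mussel probes. Per the series' design text and the labels, mussels were acclimated for 10 days at 18 °C and then kept for 7 days in clean seawater, in seawater with virgin polystyrene particles, or in seawater with polystyrene particles that had first been held with pyrene, a polycyclic aromatic hydrocarbon. Particles were under 100 µm and were dosed daily at 1.5 g/L. The loaded particles came from 6 days of mixing 20 g/L of plastic with 50 µg/L of pyrene. Each array held the RNA of 1 pool of 3 glands, and the 11 arrays comprised 4 control pools, 3 pools exposed to virgin polystyrene (PS) and 4 pools exposed to pyrene-loaded polystyrene (PS-PYR). Per the design text, another PS pool was set aside after hybridisation problems. The design text gives 3 replicates per treatment in glass beakers and does not tie pools to beakers, so pools of 1 treatment may share a beaker.

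The deposited scanner files give linear spot intensity for each array, made with Agilent Feature Extraction 11.5.1.1 per the file headers; the submitters' design text names another version of that program and another scanner model than the headers do. The processed signal used here is the spot intensity after background subtraction and multiplicative detrending, with surrogates in use for signals at or near background, per the file headers. The same deposited files carry flags for spots that are well above background, saturated or outliers. The authors also deposited a value table on a log2 scale, whose normalization is not given in the sources used here. The medians of its columns lay between 4.67 and 5.01, and its direction was taken from the Spearman correlation with the scanner signals of the same array, which lay between 0.973 and 0.991 for 10 arrays. A rank correlation does not test the scale, so folds from the authors' values assume that the scale is log2.

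The deposited scanner file of control 4 differed from the others. Copies of its spike-in control spots had a median coefficient of variation of 177%, against 10.2% to 13.4% on the other 10 arrays, and its signals correlated at 0.22 with the authors' processed values of the same array. That correlation rose along the array, from -0.02 in the first of 13 bands of the grid to 0.49 in the last, while no other array fell below 0.951 in any band. The authors' values of control 4 correlated with those of its nearest array at 0.87 (Spearman). Its scanner file was therefore left out of the reported values, which rest on 10 arrays (3 control, 3 PS and 4 PS-PYR pools). This departs from the design fixed before the data were examined, which named all 11 arrays, so counts from all 11 scanner files and from the authors' values of all 11 arrays stand beside it.

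Processed signals of non-control probes were divided by each array's 75th percentile and taken to log2. The 240 spots flagged as outliers on the 10 arrays were left out, and no probe was saturated. Probes well above background on at least 3 arrays of at least 1 group were tested, 28423 in all. Group differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, all groups in 1 fit, no covariates, and Benjamini-Hochberg adjustment over the probes of each contrast at 0.05, two-sided. Figures were drawn with matplotlib in Python. A probe not well above background on any array of a group has only a bound there, and its fold is given as "at least N-fold": the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal of any probe well above background. Arrays of the brighter group where the probe was not well above background enter at their own signal, and the bound is then only approximate.

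No gene list could be tested. Every probe's description reads unknown, its coordinate reads unmapped, and probes are named by contigs of the array's own transcript assembly, so the 28 lists of gene families fixed before the data were examined matched 0 probes. The reference table supplied holds RefSeq names without sequences, and 0 probe names could be paired with it. Probes are therefore given by identifier and 60-base sequence. The naming rule fixed before the data were examined was, for files without gene names, at most 2 probes that rose and 2 that fell per contrast, with the smallest unadjusted p filling places that no called probe took. Probes called in the authors' values are named in addition and were chosen after their values were seen.

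The arrays lay on 2 slides, each scanned in 1 session, with all 3 groups on both: slide 1 held controls 2 and 3, PS 1 and PS-PYR 3 and 4. Values with the slide as a block and within each slide were computed. The number of arrays limits the precision. On the 10 arrays, between 20.8% and 80.6% of probes were well above background. The residual standard deviation between pools of a group had a median of 0.67 on the log2 scale (10th to 90th percentile 0.37 to 1.38) over all tested probes, dim ones included. The standard deviation of 1 copy, from pairs of the same sequence on 1 array, lay between 0.10 and 0.22. It covers only pairs with both copies well above background, so the 2 spreads rest on unlike sets of probes. The fit was tested on simulated data with the fitted means and spreads of the 28423 probes, 200 of them changed. Of probes changed 4-fold, it called 0.1% for PS against control, 7.0% for PS-PYR against control and 4.5% for PS-PYR against PS; of those changed 8-fold, it called 52.8%, 61.4% and 58.2%. Alternatives covered scaling, background correction, filters, variance prior, array weights, slide, pairing by title number and leaving out each array.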

Results

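Digestive gland transcripts of mussels were compared after 7 days in clean water (control), with virgin polystyrene particles (PS) or with pyrene-loaded polystyrene particles (PS-PYR). The reported values come from 10 arrays, each of 1 pool of 3 animals, with 3 control, 3 PS and 4 PS-PYR pools. The authors' processed values cover 11 pools, including the fourth control pool. All signals below are log2 values relative to the array's 75th percentile unless the authors' processed values are named, and the adjusted p-values are those of limma. Probes carried no gene name, so they are given by identifier and 60-base sequence. The groups accounted for 24.7% of the squared distance between the 10 pools over the tested probes, and 371 of all 2100 arrangements of the pools explained as much (exact permutation test, p = 0.177). Over the 11 pools of the authors' values the groups accounted for 26.2%, which 210 of 5775 arrangements reached (exact permutation test, p = 0.0364), and 89 of the 1350 that keep each group's pools per slide (exact permutation test, p = 0.0659). The 2 slides accounted for 14.1% in the scanner signals (exact permutation test, p = 0.0873) and for 1.43% in the authors' values, the lowest of 462 splits (p = 1 in the exact permutation test), as after an adjustment for slide, so the arrangements that keep the pools per slide apply there.

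PS-PYR against control asked what pyrene-loaded particles did to the gland. In the scanner signals 1 probe rose. Probe ALL2_C67365_P (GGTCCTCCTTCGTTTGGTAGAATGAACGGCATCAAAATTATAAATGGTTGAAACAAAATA) stood at 3.87 ± 0.57 (SD, n = 4) in PS-PYR pools and at -0.73 ± 0.56 (SD, n = 3) in controls, a 24.3-fold difference (log2 4.60, SE 0.47, adjusted p = 0.033). It was well above background in 4 of 4 PS-PYR pools and in 2 of 3 controls. The difference was 4.19 within slide 1 and 5.34 within slide 2. With the slide as a block it was 4.58 (SE 0.49) and did not pass (adjusted p = 0.116). It was 28.0-fold in the authors' values (log2 4.81, SE 0.39, adjusted p = 0.0021), and 4.81 (adjusted p = 0.0097) with the slide as a block.

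In the authors' values 3 probes rose and 2 fell in PS-PYR against control; those besides ALL2_C67365_P are named after their values were seen. Besides ALL2_C67365_P, ALL2_REP_C96585_P (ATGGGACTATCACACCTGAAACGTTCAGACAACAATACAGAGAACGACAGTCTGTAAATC) stood at 5.72 ± 0.19 (SD, n = 4) in PS-PYR and was higher than in control (adjusted p = 0.0021). ALL2_C3523_S (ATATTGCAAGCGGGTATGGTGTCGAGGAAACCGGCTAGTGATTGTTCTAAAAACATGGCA) stood at 7.29 ± 0.49 (SD, n = 4) in PS-PYR and was also higher (adjusted p = 0.027), but lost its call with the slide as a block (adjusted p = 0.078). It also lost its call without control 1, 3 or 4, without PS 1 and without PS-PYR 1, 2 or 4, so that 4 of 11 fits with 1 array left out kept it, with adjusted p-values from 0.0136 to 0.150. Of the probes that fell, ALL2_C6072_S (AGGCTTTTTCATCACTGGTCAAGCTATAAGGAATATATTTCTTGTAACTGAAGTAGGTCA) stood at 7.45 ± 0.50 (SD, n = 4) in control (adjusted p = 0.0022). ALL2_C4372_P (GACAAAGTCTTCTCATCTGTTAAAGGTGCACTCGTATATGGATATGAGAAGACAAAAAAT) stood at 7.31 ± 0.22 (SD, n = 4) in control, with an adjusted p of 0.0026. The dimmer group of each of these 4 probes has only a bound, from the scanner signals. Their adjusted p-values in the authors' values therefore rest in part on the spread of values near background. For ALL2_REP_C96585_P the SD over the controls was only 0.064 (n = 4) there. In the scanner signals both fallen probes were not well above background in any PS-PYR pool, and control was at least 5.50-fold brighter for ALL2_C6072_S and at least 5.12-fold brighter for ALL2_C4372_P. The 2 other risen probes were not well above background in any of the 3 controls, and PS-PYR was at least 3.65-fold brighter for ALL2_C3523_S and at least 1.34-fold brighter for ALL2_REP_C96585_P. Both were well above background in 3 of 4 PS-PYR pools, and ALL2_C6072_S in 2 of 3 controls, so the bounds of these 3 probes are approximate. None of these 4 passed in the scanner signals (adjusted p = 0.85 for each).

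**Figure D1:**
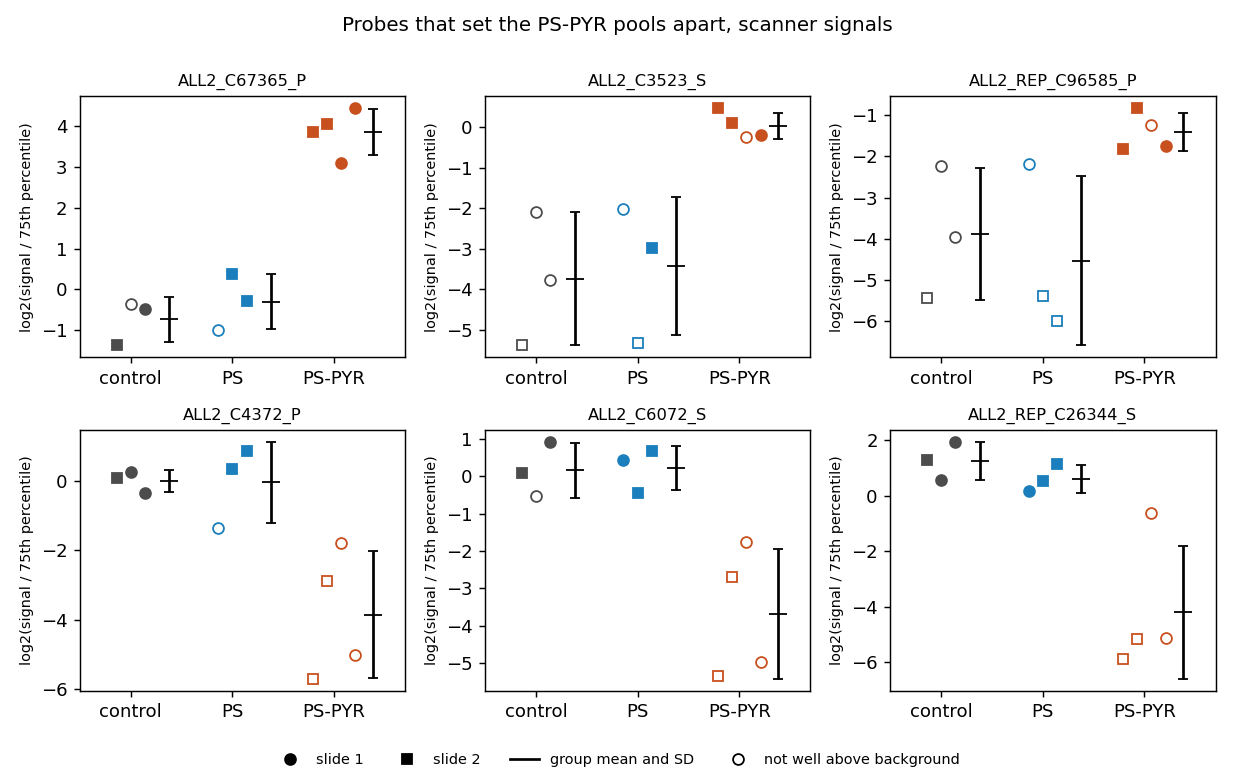
Scanner signal of 6 probes in the 10 pools used, as log2 of the processed signal over the array's 75th percentile; points are pools, circles slide 1 and squares slide 2, open symbols are not well above background, and bars give the group mean and SD. For ALL2_C67365_P the PS-PYR pools lie between 3.1 and 4.44 and every other pool at or below 0.37.

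The fixed rule named 3 more probes for this contrast that did not pass, each with an adjusted p of 0.85. ALL2_REP_C25164_N (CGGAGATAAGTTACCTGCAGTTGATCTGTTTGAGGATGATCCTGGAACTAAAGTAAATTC) stood at -0.05 ± 0.49 (SD, n = 4) in PS-PYR and at -2.01 ± 0.30 (SD, n = 3) in control. It was well above background in 3 of 4 PS-PYR pools and in only 1 of 3 controls. ALL2_REP_C26344_S (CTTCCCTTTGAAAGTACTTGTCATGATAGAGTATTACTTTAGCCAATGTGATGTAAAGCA) was well above background in 3 of 3 controls and in 0 of 4 PS-PYR pools, and control was at least 12.4-fold brighter; it passed without PS-PYR 3 (adjusted p = 0.0033), and its adjusted p ran from 0.0033 to 1 over 20 alternatives. ALL2_REP_C18872_AS (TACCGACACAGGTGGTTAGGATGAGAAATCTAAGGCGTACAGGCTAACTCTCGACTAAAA) stood at 0.36 ± 1.54 (SD, n = 4) in PS-PYR and at 4.67 ± 0.88 (SD, n = 3) in control.

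Over the 28423 probes tested for PS-PYR against control, limma called 1 higher and 0 lower, 1 higher and 0 lower with all 11 scanner files as designed, and 5 in the authors' values. At an unadjusted p below 0.05 there were 1648 probes in the scanner signals and 2279 in the authors' values, but 1128 with quantile normalization and 714 with normexp, where chance alone gives 1421 on average. Other splits of these pools gave up to 2946 in the scanner signals and 3960 in the authors' values, so counts above 1421 show no excess by themselves. The call of ALL2_C67365_P ended without control 1, 2 or 3, without PS 3 and without PS-PYR 1, 2 or 4, with adjusted p-values between 0.0709 and 0.235, while its log2 difference in these cases lay between 4.28 and 4.79. The count was 0 in these cases, except without control 3, where 2 other probes were called; it was 2 without PS-PYR 3. The count from the authors' values was 14 without control 1, 9 without PS 3 and 8 without PS-PYR 3.

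PS against control asked what the particles did without pyrene. No probe passed in either set of values: limma called 0 in the scanner signals of 10 arrays (lowest adjusted p = 0.054), 0 with all 11 scanner files and 0 in the authors' values (lowest adjusted p = 0.15). At an unadjusted p below 0.05 there were 2028 probes in the scanner signals, 1578 with quantile normalization, 2029 with normexp and 3069 in the authors' values, against 1421 by chance on average. Other splits of these pools gave up to 3198 in the scanner signals and 2988 in the authors' values. The probe with the lowest adjusted p was ALL2_REP_C20087_P (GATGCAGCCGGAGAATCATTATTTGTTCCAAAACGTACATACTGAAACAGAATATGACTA), at -2.39 ± 0.98 (SD, n = 3) in PS and 3.09 ± 0.49 (SD, n = 3) in control (log2 difference -5.48, SE 0.59). It was -4.67 and -5.89 within the slides, and -5.32 with the slide as a block (adjusted p = 0.187). It passed without PS 1 (adjusted p = 0.02), and its adjusted p was 0.0397 with quantile normalization, 0.0488 with normexp, 0.0177 with the percentile over probes above background on every array and 0.015 with a common floor. ALL2_REP_C93915_P (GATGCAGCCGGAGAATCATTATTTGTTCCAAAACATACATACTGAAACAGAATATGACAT), whose sequence is 95% identical to it over 60 bases, stood at -1.37 ± 0.76 (SD, n = 3) in PS and 3.12 ± 0.38 (SD, n = 3) in control (adjusted p = 0.12, and 0.0488 with normexp). The fourth control pool, measured in the authors' values, stood at 5.82 and 5.38 for these 2 probes, beside PS means of 5.24 ± 0.39 and 5.35 ± 1.76 (SD, n = 3), and the adjusted p-values were 0.27 and 0.34. In the scanner signals both probes were well above background in 3 of 3 controls and in 2 of 3 PS pools, so their PS means rest in part on values near background.

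**Figure D2:**
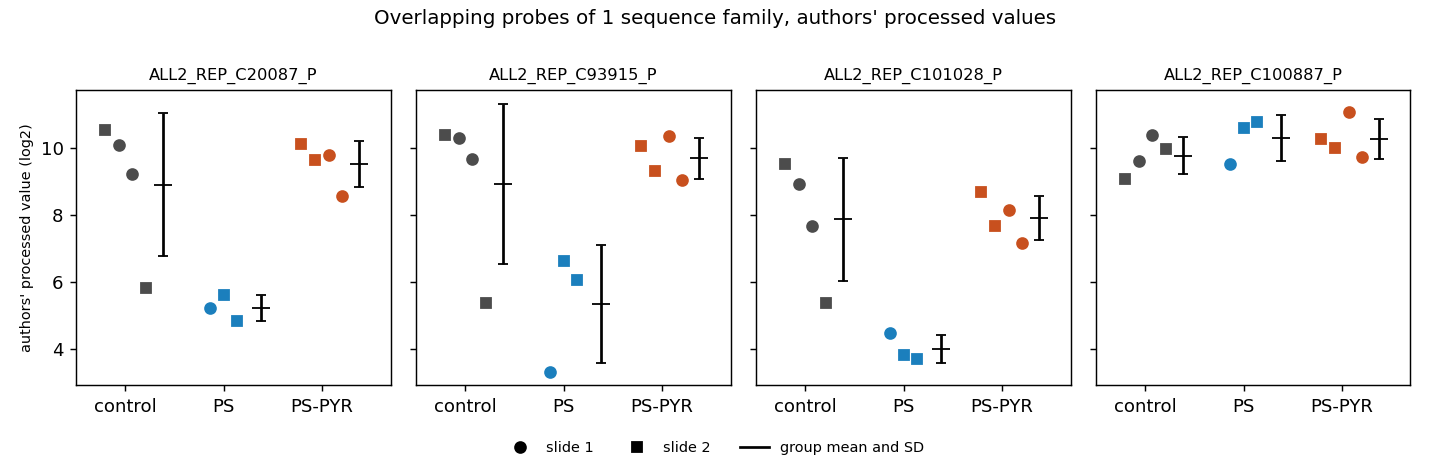
Authors' processed values (log2) of 4 overlapping probes in all 11 pools; points are pools, circles slide 1 and squares slide 2, and bars give the group mean and SD. ALL2_REP_C101028_P was not well above background in any PS pool in the scanner signals. Control 4 lies at 5.82, 5.38 and 5.39 for the first 3 probes, below the other controls, and at 9.95 for the last.

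On the other side, ALL2_REP_C41711_S (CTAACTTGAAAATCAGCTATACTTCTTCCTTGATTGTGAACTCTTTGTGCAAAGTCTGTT) stood at 5.45 ± 0.59 (SD, n = 3) in PS and 1.59 ± 1.27 (SD, n = 3) in control without passing (adjusted p = 0.26), but passed with normexp (adjusted p = 0.0488). ALL2_REP_C14372_S (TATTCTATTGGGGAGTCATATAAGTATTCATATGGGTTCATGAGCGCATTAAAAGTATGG) stood at 0.71 ± 0.53 (SD, n = 3) and -2.15 ± 0.34 (SD, n = 3), with an adjusted p of 0.28. Control 4 again stood among the PS pools for both in the authors' values, at 12.8 beside a PS mean of 12.7 ± 0.72 (SD, n = 3) and at 7.43 beside 7.82 ± 0.67 (SD, n = 3). ALL2_REP_C14372_S was well above background in only 1 of 3 controls. Detected probes at least 85% identical to ALL2_REP_C41711_S over at least 40 bases went both ways. Their log2 differences of PS from control were 2.49, 1.36, 1.34 and 0.66, and -2.98, -1.35 and -0.84. The count of 0 became 14, all lower in PS, without PS 1 and 2 without control 3. The authors' values gave 8 without control 1, 3 without control 2, and 1 without PS 2 or without PS-PYR 4.

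PS-PYR against PS tested directly what pyrene on the particles added. Against PS, 2 probes were higher and 2 lower in PS-PYR in the authors' values, and all 4 were also called against control. ALL2_C67365_P was 19.6-fold higher (log2 4.29, SE 0.42) and ALL2_REP_C96585_P was also higher, while ALL2_C6072_S and ALL2_C4372_P were lower, with only bounds on their folds. The adjusted p was 0.0063 for each of the 4. With the slide as a block the adjusted p of each was 0.0263, and ALL2_C4372_P lost its call without PS 2 (adjusted p = 0.0509). In the scanner signals ALL2_C67365_P stood at 3.87 ± 0.57 (SD, n = 4) in PS-PYR and -0.30 ± 0.68 (SD, n = 3) in PS (adjusted p = 0.068), with differences of 4.76 and 3.92 within the slides and 4.19 with the slide as a block (adjusted p = 0.157); it passed without PS 1 (adjusted p = 0.0308) and with a common floor (adjusted p = 0.0324). PS was at least 5.78-fold brighter than PS-PYR for ALL2_C6072_S and at least 4.94-fold brighter for ALL2_C4372_P, and PS-PYR at least 2.10-fold brighter for ALL2_REP_C96585_P, without passing (adjusted p = 0.9996 for each). ALL2_C4372_P was well above background in 2 of 3 PS pools and ALL2_REP_C96585_P in 3 of 4 PS-PYR pools, so these 2 bounds are approximate. In the authors' values the SD of ALL2_REP_C96585_P over the PS pools was only 0.05 (n = 3), near background, and its adjusted p rests in part on that spread.

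The other probes named for this contrast did not pass in the scanner signals as reported. ALL2_REP_C20087_P stood at 2.26 ± 0.73 (SD, n = 4) in PS-PYR and -2.39 ± 0.98 (SD, n = 3) in PS (adjusted p = 0.068); it passed without PS 1 (adjusted p = 0.0171), with the percentile over probes above background on every array (adjusted p = 0.0261) and with a common floor (adjusted p = 0.0324). ALL2_REP_C14372_S stood at -1.72 ± 0.55 (SD, n = 4) and 0.71 ± 0.53 (SD, n = 3), with an adjusted p of 0.64. ALL2_C2036_S (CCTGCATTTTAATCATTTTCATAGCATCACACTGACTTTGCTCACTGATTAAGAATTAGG) stood at -0.91 ± 0.63 (SD, n = 4) in PS-PYR and 1.27 ± 0.46 (SD, n = 3) in PS. limma called 0 of 28423 probes in the scanner signals, where 1128 had an unadjusted p below 0.05 (1421 by chance on average), 0 with all 11 scanner files, and 4 in the authors' values, where 2020 did. Other splits of these pools gave up to 2718 and 4238 at that unadjusted threshold. The count of 0 became 28, all higher in PS-PYR, without PS 1, and 1 without PS-PYR 3. Without PS 1, 26 of the 29 probes called in this contrast or in PS against control were not well above background in PS 2 or in PS 3, and 24 not in PS 1. The count of 4 became 10 without PS 3, and 8 without PS-PYR 4 or without control 2.

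The 2 exposures were set side by side through their differences from control. Across the 28423 probes, which are not independent replicates, the log2 differences of PS and of PS-PYR from control correlated at Pearson r = 0.63, and unchanged simulated groups against shared controls gave 0.54. Their covariance was 0.42 beside a simulated 0.29. The authors' values gave an r of 0.56 beside a simulated 0.46, and the covariance 0.35 beside 0.19. With the 4 control pools of the authors' values split 2 and 2, so that the exposures shared no control, r lay between 0.10 and 0.32 over 6 assignments. At an unadjusted p below 0.05 in the scanner signals, 329 probes were higher and 327 lower in both exposures, where unchanged simulated groups against shared controls gave means of 193 and 188 (20 simulations, at most 206 and 226). The simulated probes vary independently of each other, so these counts do not establish a shared response. Called lists could not be compared, as PS against control called 0. The mean of both exposed groups differed from control in 0 probes after adjustment, and in 2051 at an unadjusted p below 0.05.

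Probe names end in P, N, S or AS, suffixes whose meaning is not given in the sources used here. Of 9289 contigs with both an S and an AS probe, 5373 had at least 1 of them well above background on at least 3 arrays of a group. Both were detected for 714 contigs, the S probe alone for 3608 and the AS probe alone for 1051.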

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

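The tests of slide and scaling for ALL2_C67365_P, those of floor, slide and pool difference for the sequence family, those of exposure groups and of the slide in scanner signals for widely varying probes, and the search for 4-fold gaps were chosen after the results were seen; the other tests were stated first. Over 49 groups of 4 values, 7 held a pool far from the other 3, where chance alone would give about 2.45 for independent groups. The groups are not independent, as ALL2_REP_C26344_S counts in both sets of values. The spike-in and correlation values of control 4 had already singled out that array. The 2 counts therefore do not establish an excess.

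For control 4, the spike-in spots had a median coefficient of variation of 177%, against 10.9% to 13.4% in the other controls, and its scanner signals correlated with the authors' values at 0.22, against 0.974 to 0.990. In the authors' values, ALL2_REP_C93915_P stood at 5.38 in control 4 and between 9.67 and 10.4 in the other controls. The lowest processed signal on the array was 34.7 for PS-PYR 3, against 1.65 to 6.01 for the other PS-PYR pools. ALL2_REP_C25164_N stood at -0.78 in PS-PYR 3, where it was not well above background, and between 0.15 and 0.26 in the other PS-PYR pools. ALL2_REP_C26344_S stood at -0.63 in PS-PYR 3, also not well above background, and between -5.89 and -5.11 in the others, and in the authors' values at 5.88 against 2.83 to 3.04.

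The first pattern weighed was the higher signal of ALL2_C67365_P in PS-PYR pools. Slide or scan session would bring pools of 1 slide together, but the lowest PS-PYR pool lay at least 3.45 above the highest control pool within each slide. A local defect of the array would raise neighbouring spots, but the median difference over the 8 neighbours was -0.17 (SE 0.28). Scaling left the log2 difference at 3.46 or more, and leaving out any 1 array left it at 4.28 or more, against 4.60 as reported, although most of these settings ended the call through a higher adjusted p. These values argue against each of the 4 technical explanations, although the probe had been picked for its difference on these same pools. A sequence variant or a difference between pools unrelated to exposure was not tested for this probe, and pools of 1 treatment may share a beaker. A response to pyrene-loaded particles stays a hypothesis, found and tested on the same pools. At least as many called probes as the real 1 came from 7 of 35 splits of these pools.

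The second pattern was the lower signal of 3 overlapping probes (ALL2_REP_C20087_P, ALL2_REP_C93915_P and ALL2_REP_C101028_P) in PS pools; none passed as reported. The lowest control value lay only 1.05 above the highest PS floor, so a higher floor on the PS arrays does not account for all of the difference. Its share of the size stays open, as PS 1 was not well above background for any of the 3 probes. For ALL2_REP_C101028_P no PS pool was well above background. With control 4 left out, the lowest control pool lay at least 2.94 above the highest PS pool within each slide. That smallest gap was for ALL2_REP_C101028_P on slide 1, with PS 1 not well above background. Each slide then held only 1 pool of 1 of the 2 groups: PS 1 on slide 1 and control 1 on slide 2. These gaps therefore argue against the slide only for the pools used. Both tests first took all 5 detected members and were then limited to these 3, after the slide test over 5 had been seen. A sequence variant among the pooled animals stays open: ALL2_REP_C100887_P and ALL2_REP_C37467_P, which share 1 sequence that is 90% identical to ALL2_REP_C101028_P over 60 bases, were not lower in PS, at up to 0.37. A difference between pools unrelated to exposure may also account for it, since in the authors' values the gap between the lowest control pool, control 4, and the highest PS pool was at most 0.90; on slide 2, control 4 stood at 5.82 for ALL2_REP_C20087_P and 5.38 for ALL2_REP_C93915_P, with PS pools up to 5.63 and 6.62.

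The third pattern was that 3545 of 28423 probes (12.5%) varied over 16-fold between the 11 pools in the authors' values. Noise of single spots does not account for it: 25 pairs of copies of identical sequence correlated at a median of 0.99 over the pools, with 22 pairs above 0.8 and the lowest at 0.20. Both copies lie on the same array, so this does not speak to differences between whole arrays. The widest gap set 1 exposure group apart in 11 of these probes (0.31%), so few were cleanly parted by exposure. A group shift with 1 stray pool would be missed, so exposure as a source is not excluded. The gap parted the pools by slide in 0 (0%). That decides nothing, as the slides held less of the distance in these values (1.43%) than any other split. Over these probes in the scanner signals, the slides explained 12.3% of the squared distance (highest other split 22.2%). The probes had been chosen in the authors' values, where the slides held so little, so this does not exclude the slide. The widest gap set a single pool apart in 1800 (50.8%), most often PS 1 (413), PS-PYR 3 (280) and PS-PYR 2 (205). Of the 10 arrays used, PS-PYR 3 had the lowest share of probes well above background (20.8%). PS-PYR 2 had the highest (80.6%), and PS 1 had 23.7%. Array-wide differences in signal and differences between the animals pooled remain candidate explanations that were not tested.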

How the results depend on the processing

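Fits of the authors' values beyond the plain one, the fit of all 11 scanner files, the common floor, the kept outlier spots and the pooled exposures were chosen after seeing the data. Counts follow in the order PS against control, PS-PYR against control and PS-PYR against PS, with 0, 1 and 0 as reported; the cause of a moved count was not tested unless stated. They were 1, 0 and 0 with quantile normalization, 3, 0 and 0 with normexp, 0, 5 and 4 in the authors' values, 1, 1 and 1 with the 75th percentile over probes well above background on every array, 1, 1 and 2 with a trend and robust prior, 3, 1 and 2 with array weights, and 1, 1 and 2 with a common floor. They were 0, 0 and 0 with no filter on dim probes, with probes well above background on every array (which leaves out ALL2_C67365_P), with only the 2 groups compared in the fit, with slide or scan date as a block (the same split) and at an adjusted p below 0.01. They were 0, 1 and 0 with 1.5-fold or 2-fold minima, by sequence name, with outlier spots kept and with all 11 scanner files. The percentile over probes above background on every array moved the median log2 difference to 0.14, 0.31 and 0.19.

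Leaving out 1 array gave 0 to 14, 0 to 2 and 0 to 28 probes. Without PS 1 the counts were 14, 1 and 28, without control 3 they were 2, 2 and 0, and without PS-PYR 3 they were 0, 2 and 1; PS-PYR against control fell to 0 without control 1 or 2, PS 3, or PS-PYR 1, 2 or 4. The authors' values gave counts of 0, 4 and 4 with the slide as a block, 2, 9 and 5 with array weights, and 0, 8 and 3 with a trend and robust prior. Leaving out 1 array gave 0 to 8, 4 to 14 and 4 to 10 there: 8, 14 and 5 without control 1, 3, 5 and 8 without control 2, 1, 6 and 5 without PS 2, 0, 9 and 10 without PS 3, 0, 8 and 5 without PS-PYR 3, and 1, 6 and 8 without PS-PYR 4.

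The title numbers' final digit as a replicate block gave 0, 0 and 0 probes, with ALL2_C67365_P at 4.48 (adjusted p = 0.43) in PS-PYR against control. Whether the digits pair the pools stays open. Same-digit pools deviated together at correlations from -0.003 to 0.26 (mean 0.14, 5 of 8 over 0.1, those near 0 all of digit 3), other pools at a mean of -0.04 (5 of 25 over 0.1), so the bar for pairing, every pair over 0.1, was missed; control 1 correlated best with PS 3 (0.24), of another digit. The authors' values gave -0.24 to 0.39 (mean 0.08, 5 of 10 over 0.1). The correlation of the exposures' differences from control ran from 0.56 to 0.74 with 1 array left out (jackknife SE 0.17). Of 241 alternatives for the 12 named results, 214 kept direction and side of the threshold, 13 lost the call, 14 gained one and 0 reversed. The 13 were all for ALL2_C67365_P in PS-PYR against control, the only named result that passed as reported, which kept its call in 7 of 20 alternatives. For the other named results, keeping the side of the threshold means that they stayed uncalled. Camera, its estimated correlation and fry were not run, as no list matched a probe. Signal over background limits dim probes, as the lowest signal ran from 1.65 to 34.7 between arrays.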

Other observations

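The search for 4-fold gaps and the splits that keep each group's pools per slide were chosen after the results were seen, and the other tests were stated first. In the authors' values, a gap of at least 4-fold set all 4 PS-PYR pools apart from the other 7 pools for 4 probes: ALL2_C67365_P, at 7.20-fold, and ALL2_C4372_P, ALL2_C6072_S and ALL2_REP_C96585_P, whose gaps are not given because their dimmer pools include a group not well above background on any array. Of the 330 ways to pick 4 pools, 4 gave as many, with a highest other count of 13 for control 2, control 4, PS 1 and PS-PYR 2. As these probes had been called before the search was set up, this count does not exclude chance. The same search gave 0 probes for control (highest other 13 over 330 sets) and 0 for PS (highest other 15 over 165 sets of 3 pools, for controls 2, 3 and 4); as any set reaches 0, these counts say nothing about chance.

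Other splits of the pools bear on the counts of limma. In the scanner signals, PS against control has only 10 splits, too few for a share under 0.05; the real count was 0 (2028 at an unadjusted p below 0.05) and the highest other 10. For PS-PYR against control 7 of 35 splits gave at least the real count of 1 (highest other 11), so chance was not excluded. Limma's count was 0 for PS-PYR against PS in the scanner signals (1128 at an unadjusted p below 0.05; highest other 2) and 0 for PS against control in the authors' values (3069; highest other 8); all 35 splits reach 0 in each, so these counts say nothing about chance. With the authors' values, 3 of 35 gave at least the 5 of PS-PYR against control (highest other 8), and 2 of 35 at least the 4 of PS-PYR against PS, so chance was not excluded for these. The highest other in the last was 114, for PS 2, PS 3, PS-PYR 1 and PS-PYR 4 against the other 3. It changes the number of pools per slide. Those 4 arrays had 52.8% to 58.6% of probes well above background, against 23.7%, 80.6% and 20.8% on PS 1, PS-PYR 2 and PS-PYR 3. The source of this split was not tested. With each group's pools per slide kept, 3 of 18 splits reached 5 against control (highest other 8). Against PS, 1 of 18, the real split, reached 4 (highest other 3), too few for a share under 0.05. At an unadjusted p below 0.05, the real split of the authors' values was the only 1 of 35 to reach 3069 for PS against control (highest other 2988). The slides held less of the distance in these values (1.43%) than any other split, so the 18 splits that keep each group's pools per slide apply (highest other 2278), too few for a share under 0.05; in the scanner signals 3 of 10 splits reached the real 2028 (highest other 3198), again too few for a share under 0.05. Of the 35 splits of the authors' values, 4 reached 2279 for PS-PYR against control (highest other 3960) and 10 reached 2020 for PS-PYR against PS (highest other 4238), so chance was not excluded for these.

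Over all probes, 371 of 2100 arrangements explained as much of the squared distance between pools as the exposure groups, at 24.7% (highest other 30.4%), so chance was not excluded in the scanner signals; in the authors' values 210 of 5775 did, at 26.2% (exact permutation test, p = 0.0364), but with each group's pools per slide kept 89 of 1350 did (exact permutation test, p = 0.0659; highest other 30.3%), so chance was not excluded there either. For the 2 slides 11 of 126 splits explained as much as 14.1% (highest other 20.8%). The statement made first took 5% or more as excluding the slide, which was too strong, since a p that misses the threshold excludes nothing; a slide effect stays open.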
